A study of Danio rerio with 8 samples.

How the data were processed

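RNA was measured in 8 single zebrafish larvae at 6 days post fertilization, 4 wild-type siblings and 4 siblings homozygous for osgep G177A. Per the labels' protocols, each larva was homogenised on its own, its total RNA was purified with a DNase step, and libraries were made after depletion of ribosomal RNA with random priming and sequenced on an Illumina NovaSeq instrument. The deposited table holds estimated counts per gene for the 8 larvae in a single matrix. Per the submitters' processing notes, the tools were Trimmomatic, STAR 2.7 and RSEM and the genome build was danRer11; their settings, the gene annotation and the strand setting were not given in the sources used here. RSEM divides reads that match several genes among them, so values of near-identical paralogs, such as the chemokine, crystallin and opsin clusters, are uncertain, and reads from overlapping or antisense genes may be counted together. Between 88.0% and 90.9% of values per library were whole numbers, and the library totals ranged from 14398812 to 19052599.

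The table had 35197 rows, of which 28689 carried an Ensembl gene identifier, and 710 rows shared a symbol or identifier with another row and are uncertain. Of the 28489 distinct identifiers, 25745 were present in the table of gene names. Rows with no gene name numbered 0, as did columns of other samples. Estimated counts were rounded to whole numbers. Rows were filtered with filterByExpr at a minimum count of 10, which left 21447, and scaled with TMM factors between 0.732 and 1.23. CPM values were computed on the scaled library sizes. Genes were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, genotype as the only term) and Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the fold change and its F statistic. The labels give replicate numbers but no clutch, tank or day, so no pairing was used. Larvae are separate animals, and p-values measure the spread between these larvae.

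In total 49 gene lists, covering pathways, organelles and the cell types of a larva, were fixed before the data were examined. Of 2027 gene names on them, 1951 were found, and 48 lists had at least 5 tested members; the list of mitochondrial genome-encoded mRNAs had 0 rows. Lists were tested with camera in limma 3.58.1 after voom, with a preset correlation between genes of 0.01, and adjusted over the lists. Camera compares a list with the other genes, whereas fry asks whether its members move, on balance, to the same side. The mean log2 CPM of each list per larva (prior count 2) was compared by an exact two-sided permutation test.

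The genes named were chosen by a rule fixed before the data were examined. It takes osgep and the measured KEOPS members, and, among genes past the threshold with non-overlapping groups, a mean of at least 2 CPM in the higher group and an assigned symbol, the 10 largest rises, the 10 largest falls and the 5 smallest p-values each way. It adds up to 4 members with the smallest p from each list that passed, and from the lists of the integrated stress response, unfolded protein response, p53, cell cycle, neural progenitors and podocytes whether or not they passed, of which the text leaves out some. Genes named outside the rule are identified as such.

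The test of genes near osgep had been planned in megabase windows. The gene table available was of GRCz12tu, not the build of the counts, so windows of 100 annotated genes on each side replaced them and no coordinates are given; 18288 of the tested rows (85.3%) had a place in that gene order.

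The steps were tested on simulated data with the real means and library sizes and 200 changed genes. For this comparison edgeR, run on 21082 simulated genes, recovered 43% of genes changed 2-fold and 90.6% of those changed 4-fold, with 9 false calls among 139. DESeq2, run on 21447, recovered 58% and 89% with 33 false calls among 180. With no gene changed edgeR made 1 false call and camera called 0 lists; simulated genes were independent of each other, so that test does not show how camera behaves when the genes of a list vary together between larvae. No pair of libraries in a group differed by as little as sampling noise (chi-square per degree of freedom 19.4 to 73.6).

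Alternatives fixed beforehand were other size factors, no filter and a stricter filter at a minimum count of 50, DESeq2 1.42.0, limma voom, a fit without the robust option, removal of the 100 most abundant rows, removal of the ribosomal or mitochondrial RNA row, a test against a 1.5-fold change, a replicate block and leaving out each library in turn. Scaling by library totals alone, leaving out wild-type 1 and homozygote 2 together, adding 1 surrogate variable from sva 3.50.0 and the windows counted in genes were added after the data were seen. The surrogate variable was -0.302, 0.43, 0.317 and 0.338 in wild-type larvae 1 to 4. In homozygotes 1 to 4 it was -0.052, 0.204, -0.349 and -0.586. It thus overlaps with genotype, and a call lost with it does not show that genotype had no part. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.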

Results

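Whole-larva RNA was profiled in 8 zebrafish at 6 days post fertilization, each library coming from a single larva. The larvae fell into 2 groups of 4: wild-type siblings and siblings homozygous for the osgep G177A allele, which inherited it from parents that were not themselves homozygous mutants. osgep encodes the catalytic subunit of KEOPS, the complex that makes the N6-threonylcarbamoyl modification of transfer RNA. Estimated gene counts totalled between 14398812 and 19052599 per library, and 21447 gene rows were abundant enough to test. The comparison asks how the transcriptome of larvae homozygous for the allele differs from that of their wild-type siblings.

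Genes called lower in homozygous larvae included 16 of 39 on the neutrophil and macrophage lists and 8 of 36 on the inflammation list. Genes called higher included 3 of 22 for cytosolic aminoacyl-tRNA synthetases, 3 of 32 of the endoplasmic reticulum unfolded protein response and several of amino acid metabolism, a theme named after the results were seen. With an estimated correlation camera called 0 of 48 gene lists (2 at an unadjusted p under 0.05; fry called 2). The granule enzyme gene mpx, a standard neutrophil marker, was 4.82-fold lower, at 85.3 ± 18.7 CPM (scaled counts; SD, n = 4) in wild-type and 17.7 ± 2.77 CPM (SD, n = 4) in homozygous larvae. grn1, a granulin gene, was 9.22-fold lower. In the other direction, bcat1, which encodes a branched-chain amino acid transaminase, was 2.31-fold higher, and hyou1, which encodes a chaperone of the endoplasmic reticulum, was 2.22-fold higher.

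osgep itself fell in the homozygotes. Its level was 7.46, 11.5, 10.1 and 5.55 CPM in wild-type larvae 1 to 4 and 2.60, 3.68, 1.64 and 2.99 CPM in homozygous larvae 1 to 4, so that no homozygote reached the lowest wild-type value. The log2 fold change was -1.66 (SE 0.29, adjusted p = 0.019 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By edgeR the call was lost without wild-type 2 (adjusted p = 0.0722), wild-type 3 (0.0855), homozygote 1 (0.0608) or homozygote 3 (0.0516), with the direction kept. It was also lost with libraries scaled by totals alone (log2 fold change -1.28, adjusted p = 0.0536), with 1 surrogate variable in the fit (-1.46, 0.0756) and against a 1.5-fold change (0.119). Over all alternatives the adjusted p ranged from 3.9e-05 to 0.119. The other 4 measured members of the KEOPS and t6A synthesis list did not pass the test, and osgep was also the only member lower when adjusted over the list alone. Their log2 fold changes were 0.35 for tprkb, -0.18 for tp53rk, -0.40 for osgepl1 and -0.03 for yrdc, and those of tp53rk and yrdc turned positive when libraries were scaled by their totals alone (0.21 and 0.38). The list was not called (camera adjusted p = 0.296); its median log2 fold change was -0.18, or 0.21 with that scaling, where the median of all genes moved from 0.02 to 0.40.

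**Figure D1:**
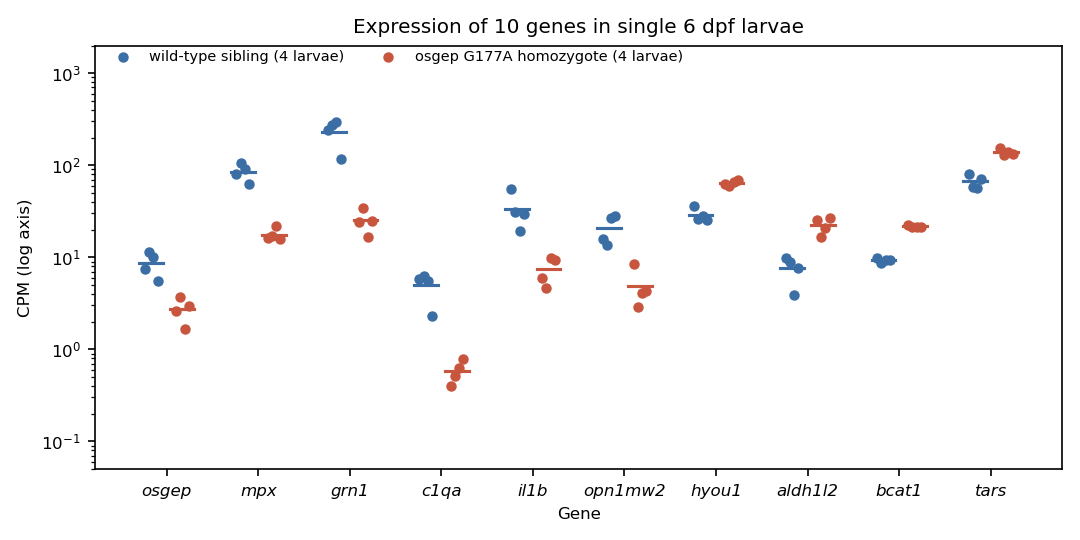
CPM of 10 genes on a log axis, with a point for each of the 4 wild-type and 4 homozygous larvae and a line at each group mean. In every gene shown the groups do not overlap: the homozygotes lie below the wild-type larvae for osgep, mpx, grn1, c1qa, il1b and opn1mw2, and above them for hyou1, aldh1l2, bcat1 and tars.

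Across all rows, 226 genes changed at an adjusted p below 0.05 (edgeR), 61 of them higher and 165 lower in homozygotes. The values of the groups did not overlap in 224 of these genes. Over all tested rows this was so in 2241 (10.4%), where chance gives 2.86% on average over random divisions of the larvae. Genes vary together between larvae, so a single division can lie far from that average. The share was not computed for other divisions, so no excess is read from it. The count of changed genes rests on which libraries are in: it was 2130 without wild-type 1, 72 without wild-type 2, 38 without wild-type 3, 58 without homozygote 1, 1158 without homozygote 2, 69 without homozygote 3 and 105 without homozygote 4. Without wild-type 1 and homozygote 2 together, a pair chosen because it stood apart, the count was 3952 of 21545 rows. List counts in that setting stand beside that share. Scaling by library totals alone, a setting added after the data were seen, shifted the median log2 fold change of all rows to 0.40 and gave 88 higher and 35 lower genes, so directions here are relative to the bulk of genes after TMM scaling. With all 8 libraries 4773 of the 21447 rows had an unadjusted edgeR p under 0.05. Adjustment over a list alone is therefore passed more easily than adjustment over all rows.

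Neutrophil and macrophage genes were 16 of the 165 lower genes. Of 13 neutrophil genes tested, 6 fell, 0 rose and 7 did not pass, and 11 were lower when p-values were adjusted over the list alone. The collagenase gene mmp13a was 5.05-fold lower (log2 fold change -2.34, SE 0.32), the NADPH oxidase subunit gene ncf1 3.93-fold lower and npsn, a neutrophil protease gene, 3.88-fold lower. Of 26 microglia and macrophage genes, 10 fell, 0 rose and 16 did not pass, and 21 were lower when adjusted over the list alone. The complement genes c1qa and c1qb were 8.36-fold and 9.96-fold lower, at only 0.581 ± 0.170 and 0.202 ± 0.0731 CPM (SD, n = 4) in homozygotes. cd74b, which encodes an invariant chain of antigen presentation, was 3.13-fold lower. ccl34b.1, a chemokine gene of the same list, was 5.58-fold lower, a call lost without wild-type 2, 3 or 4 or homozygote 1, 3 or 4 (highest edgeR adjusted p 0.0836). The call of ncf1 was lost without homozygote 1 (0.056) or homozygote 4 (0.0515); mpx, mmp13a, npsn, grn1, c1qa, c1qb and cd74b were called whichever library was left out. The calls of mmp13a (0.0965), npsn (0.0919) and ccl34b.1 (0.132) were lost with 1 surrogate variable, and with libraries scaled by totals alone those of ncf1 and ccl34b.1 (0.0536 each). The counts of called genes moved with the libraries. Of the macrophage genes 5 fell without wild-type 2 or 3 or homozygote 1, 3 or 4, and 17 fell without wild-type 4. Of the neutrophil genes 3 fell without homozygote 1, and 9 fell without wild-type 1 or homozygote 2. Both lists were called by camera at its preset correlation (adjusted p = 2.1e-12 and 1.35e-15). Their adjusted p = 0.431 with an estimated correlation, and 0.0383 by fry, the rotation test. The mean of each list was lower in each homozygote than in any wild-type larva (exact permutation p = 0.0286 for each, the smallest that 4 against 4 allows, and 0.211 after adjustment over 48 lists).

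Some genes of inflammatory signalling fell as well. Of 36 genes on the inflammation and acute phase list, 8 fell, 0 rose and 28 did not pass. Of the 36, 24 lay below 0 and 12 above, and 16 were lower when adjusted over the list alone. The list median of -0.490 was -0.081 without wild-type 1 and homozygote 2, where 9 fell and 2 rose and the list was not called (camera adjusted p = 0.139). It was -0.137 with libraries scaled by totals alone, where 1 fell, and -0.815 with 1 surrogate variable, where 11 fell. il1b, the interleukin-1 beta gene, was 4.51-fold lower at 7.43 ± 2.58 CPM (SD, n = 4) against 33.7 ± 15.05 CPM (SD, n = 4), the chemokine gene cxcl11.1 was 5.98-fold lower, the NF-kappa-B inhibitor gene nfkbiab was 2.00-fold lower and the tumour necrosis factor gene tnfb was 2.15-fold lower. By edgeR the call of il1b was lost without wild-type 2, homozygote 1 or homozygote 4 (highest adjusted p 0.0791), and that of tnfb without wild-type 2, wild-type 3 or homozygote 1, 3 or 4 (highest adjusted p 0.0952). With libraries scaled by totals alone the calls of il1b (0.054), nfkbiab (0.0695) and tnfb (0.0833) were lost. The list was called by camera (adjusted p = 8.52e-05), with adjusted p = 0.685 with an estimated correlation. Its means overlapped between the groups (exact permutation p = 0.0857). With a single library left out, between 2 and 9 of its genes fell. Other large falls by the naming rule were in the chemokine genes ccl34b.8 (14.1-fold) and cxcl11.6 (8.08-fold), the Fc receptor gamma-like gene fcer1gl (6.20-fold), the itaconate enzyme gene acod1 (5.51-fold), ms4a17a.6 (5.49-fold) and ripk3, a necroptosis kinase gene (4.00-fold). Of these, ccl34b.8, fcer1gl and ripk3 were called whichever library was left out. Without homozygote 1 the edgeR adjusted p was 0.139 for cxcl11.6, 0.118 for acod1 and 0.0562 for ms4a17a.6; the calls of cxcl11.6 and acod1 were also lost without wild-type 2 or homozygote 3, that of acod1 without homozygote 4, that of cxcl11.6 without wild-type 3 or 4, and that of ms4a17a.6 without wild-type 2 or 3. The calls of cxcl11.6 and acod1 were lost with library totals too (0.0579 and 0.0536), and that of cxcl11.6 with the surrogate variable (0.0756). acod1 is also on the inflammation list. In homozygotes the mean was only 0.28 CPM for ccl34b.8, 0.67 for cxcl11.6 and 0.86 for cxcl11.1, so their folds rest on few counts.

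Some genes of the integrated stress and unfolded protein responses rose. On the list of the integrated stress response and targets of its transcription factor ATF4, 5 of 42 genes rose, 1 fell and 36 did not pass; 12 were higher and 5 lower when adjusted over the list alone. The mitochondrial folate enzyme gene aldh1l2 was 2.94-fold higher, the transcription factor gene atf5b 2.07-fold higher and the serine synthesis gene psat1 1.68-fold higher, while cebpb, a transcription factor gene, fell by 1.43 on the log2 scale. The other 2 risers, atf5a and asns, were 1.96-fold and 2.14-fold higher, and atf4a and chac1, which did not pass, had log2 fold changes of -0.66 (SE 0.19) and -0.78 (SE 0.23); these 4 genes were singled out after their values were seen. Only cebpb among the 6 was called whichever library was left out. By edgeR the call was lost for aldh1l2 without homozygote 1 (adjusted p = 0.0516) and for atf5b without wild-type 3 or homozygote 1 (highest 0.0855). It was lost for psat1 and atf5a without wild-type 2 or 3 or homozygote 1 or 3 (highest 0.0855 and 0.123), and for asns without wild-type 2, 3 or 4 or homozygote 1, 3 or 4 (highest 0.137). Once 1 surrogate variable was added to the fit, 1 gene of the list rose and 1 fell, as the calls of aldh1l2 (0.0692), atf5b (0.058), atf5a (0.0639) and asns (0.13) were lost. With library totals 7 rose and that of cebpb was lost (0.0538). The list was called by camera (adjusted p = 0.0429) but not without wild-type 1 (0.0501), wild-type 4 (0.0787), homozygote 2 (0.0719) or homozygote 4 (0.0935), and its adjusted p = 0.685 with an estimated correlation. Of 32 genes of the unfolded protein response, 3 rose, 0 fell and 29 did not pass, with 8 higher when adjusted over the list alone; beside hyou1, the chaperone genes dnajb11 and calr were 1.88-fold and 1.76-fold higher, and both calls were lost without wild-type 2, 3 or 4 or homozygote 1, 3 or 4 (highest edgeR adjusted p 0.137 and 0.151). Both were also lost with 1 surrogate variable (0.0763 and 0.105) and with library totals (0.0514 and 0.0536), where 1 gene of the list rose. pdia4 had a log2 fold change of 0.78 (adjusted p = 0.0588 by edgeR). This list was called by camera (adjusted p = 0.000201; adjusted p = 0.685 with an estimated correlation). The means of both lists were higher in each homozygote than in any wild-type larva (exact permutation p = 0.0286 each, 0.211 after adjustment over 48 lists). For the integrated stress response the gap was narrow, with homozygote 2 at 0.085 and wild-type 1 at 0.065 relative to the wild-type mean.

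Of 22 genes for cytosolic aminoacyl-tRNA synthetases, the enzymes that charge transfer RNA, 3 rose, 0 fell and 19 did not pass, with 5 higher when adjusted over the list alone. tars, for threonine, was 2.09-fold higher at 139 ± 10.1 CPM (SD, n = 4) against 66.7 ± 11.3 CPM (SD, n = 4), and nars, for asparagine, was 1.83-fold higher; cars, for cysteine, rose by 1.07 on the log2 scale. Each of these 3 calls was lost without wild-type 3 (edgeR adjusted p = 0.0611 for tars, 0.0634 for cars and 0.0845 for nars). The list was called by camera (adjusted p = 0.0219; adjusted p = 0.685 with an estimated correlation), but not without wild-type 1 (0.12), homozygote 1 (0.0538) or homozygote 2 (0.256). Its means overlapped between the groups (exact permutation p = 0.0857). Among the largest rises by the naming rule were also the neutral amino acid transporter gene slc1a4 (2.27-fold), the sialidase gene neu3.3 (3.76-fold), ppp1r3b, for a glycogen-targeting phosphatase subunit (3.16-fold), adm2a, for an adrenomedullin-like peptide (2.84-fold), the phosphate transporter gene slc34a2a (2.32-fold), fndc7rs4 (2.45-fold) and ogt.1, for O-GlcNAc transferase (2.28-fold). Without wild-type 3 the edgeR adjusted p was 0.0595 for neu3.3, 0.0562 for adm2a, 0.0672 for slc34a2a, 0.156 for fndc7rs4 and 0.133 for ogt.1; the calls of slc34a2a, fndc7rs4 and ogt.1 were also lost without wild-type 2, those of fndc7rs4 and ogt.1 without homozygote 3 or 4, and that of ogt.1 without wild-type 4 or homozygote 1. Adding 1 surrogate variable ended the calls of neu3.3 (0.0692), fndc7rs4 (0.261) and ogt.1 (0.115), and library totals that of ogt.1 (0.0536). bcat1, hyou1, ppp1r3b and slc1a4 were called whichever library was left out. On the heat shock list 1 of 27 genes rose, the collagen chaperone gene serpinh1b (3.58-fold; adjusted p = 0.0618 by edgeR without wild-type 3), 0 fell and 26 did not pass, with dnaja1 at a log2 fold change of 0.88 (adjusted p = 0.0521 by edgeR); 7 were higher when adjusted over the list alone. That list was called by camera (adjusted p = 0.0396; adjusted p = 0.685 with an estimated correlation), and not without wild-type 1 or 3 or without homozygote 1, 2 or 4 (highest adjusted p 0.0935).

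Photoreceptor genes were the sensory group with calls. Of 51 tested, 4 fell, 0 rose and 47 did not pass, with 14 lower and 3 higher when adjusted over the list alone. The green cone opsin gene opn1mw2 was 4.29-fold lower, the cone transducin subunit gene gngt2a 2.41-fold lower, the retinal transcription factor gene crx 1.99-fold lower and prph2b, for an outer segment protein, 1.81-fold lower. Without wild-type 3 none of these 4 was called (edgeR adjusted p between 0.0615 for opn1mw2 and 0.169 for prph2b). Calls were also lost without wild-type 2 for gngt2a, crx and prph2b, without wild-type 4 for prph2b, without homozygote 1 for crx and prph2b, without homozygote 3 for opn1mw2, crx and prph2b, and without homozygote 4 for opn1mw2, gngt2a and prph2b. All 4 were lost with 1 surrogate variable (0.124 for opn1mw2, 0.0641 for gngt2a, 0.0756 for crx and 0.186 for prph2b) and with library totals (0.0536, 0.0624, 0.113 and 0.0862). DESeq2 called 12 genes of the list lower and 2 higher. The list was called by camera (adjusted p = 0.000243; adjusted p = 0.685 with an estimated correlation). Its median log2 fold change was -0.30, and 0.07 when libraries were scaled by totals alone, or -0.33 relative to the median of all genes, which that scaling moved to 0.40. The list mean was lower in each homozygote than in any wild-type larva (exact permutation p = 0.0286, 0.211 after adjustment over 48 lists).

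With all 8 libraries the lists fixed for the pathways linked to KEOPS disease showed few calls by edgeR. Their counts without wild-type 1 and homozygote 2 come from a fit that called 3952 of 21545 rows. Of 41 p53 and apoptosis genes, the cell cycle inhibitor gene cdkn1a rose (2.05-fold), the cell death gene pmaip1 and the spermidine acetyltransferase gene sat1a.2 fell (2.07-fold and 1.72-fold) and 38 did not pass, with 3 higher and 4 lower when adjusted over the list alone; the calls of all 3 were lost without wild-type 2, wild-type 3, homozygote 1 or homozygote 3, those of cdkn1a and sat1a.2 also without homozygote 4 and that of sat1a.2 without wild-type 4 (highest edgeR adjusted p 0.142 for cdkn1a, 0.099 for pmaip1 and 0.165 for sat1a.2). The surrogate variable ended the calls of cdkn1a (0.061) and sat1a.2 (0.119), and library totals those of pmaip1 (0.1) and sat1a.2 (0.101). The list median was 0.128, or 0.302 without wild-type 1 and homozygote 2, where 7 genes rose and 3 fell, and -0.076 with the surrogate variable, where 0 rose and 2 fell. DESeq2 called 3 higher and 4 lower. The list was not called (camera adjusted p = 0.719), but camera asks for a shift in a shared direction. Fry's mixed test, which counts changes in either direction, gave an unadjusted p = 1.06e-06. It gave 0.0044 for the cell cycle list, 0.00236 for neural progenitors and 0.0046 for podocytes. These lists may thus hold changes that the tests of direction miss. Of 60 cell cycle genes, the phosphatase gene cdc25b fell (1.87-fold), 0 rose and 59 did not pass, with 2 higher and 3 lower when adjusted over the list alone; cdc25b was not called without wild-type 2 or 3 or homozygote 1, 3 or 4 (highest edgeR adjusted p 0.103) or with library totals (0.114). ccnb1, bub1 and ccnd1 had log2 fold changes of -0.80, -0.79 and 0.61. The list was called lower by camera (adjusted p = 0.0139; adjusted p = 0.685 with an estimated correlation), but not without wild-type 4 (0.0847) or homozygote 3 (0.195), and its median was -0.25, or 0.14 with libraries scaled by totals alone, which is -0.26 relative to the median of all genes. It was -0.088 with 1 surrogate variable, and -0.398 without wild-type 1 and homozygote 2, where 11 genes fell and 4 rose. The means of the cell cycle list overlapped between the groups (exact permutation p = 0.171). Of 47 neural progenitor genes none passed (camera adjusted p = 0.755), where edgeR called 2 higher and 2 lower when adjusted over the list alone; pax6b had a log2 fold change of 0.92 and eomesa of -0.97. The median of that list was 0.03 and its mean -0.04. Without wild-type 1 and homozygote 2, 5 of its genes rose and 4 fell (median 0.012), and DESeq2 called 2 higher and 2 lower. Of 27 podocyte genes, mafbb, a transcription factor gene also known from macrophages, fell (2.91-fold) and 26 did not pass, with 1 lower when adjusted over the list alone and itga3b at a log2 fold change of 0.70. mafbb was not called without wild-type 2, wild-type 3, homozygote 1 or homozygote 4 (highest edgeR adjusted p 0.0855), with 1 surrogate variable (0.164) or with library totals (0.0536), and the podocyte list was not called (camera adjusted p = 0.507; median 0.05, mean -0.12). Its median was -0.069 with the surrogate variable, and 2 of its genes rose and 3 fell without wild-type 1 and homozygote 2. Other cells of the larva may hold transcripts of the podocyte list, so whole-larva RNA could hide a change in podocytes.

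Ribosomal protein, oxidative phosphorylation and muscle genes had lower values in most homozygotes, without a single gene passing over all rows in the edgeR fit of all 8 libraries with genotype alone. DESeq2 called 70, 22 and 11 genes of these lists lower, and edgeR with the replicate block 3, 3 and 4. Without wild-type 1 and homozygote 2, 74 ribosomal protein genes fell and 1 rose, and 85 oxidative phosphorylation and 36 muscle genes fell (medians -1.099, -0.895 and -0.631). Without wild-type 1 alone 69, 49 and 11 genes fell and 1 ribosomal protein gene rose. Without homozygote 2 alone 31, 35 and 22 fell. Leaving out any other single library gave no call on these lists. With 1 surrogate variable in the fit the medians shrank to -0.369, -0.182 and -0.112. Of 89 ribosomal protein genes 78 had a log2 fold change below 0 (median -0.78; rps26 -0.83, rpl22l1 -0.63), and 74 were lower when adjusted over the list alone. Of 99 nuclear-encoded oxidative phosphorylation genes 97 lay below 0 (median -0.58; atp5md -1.05), and 51 were lower when adjusted over the list alone. Of 65 skeletal muscle genes 46 lay below 0 (median -0.37; atp2a1l -1.10), and 0 passed when adjusted over the list alone. Camera called the 3 lists (adjusted p = 1.97e-19, 7.68e-18 and 0.000201 for oxidative phosphorylation, ribosomal proteins and muscle), each with adjusted p = 0.685 with an estimated correlation. In the ribosomal protein and oxidative phosphorylation lists wild-type 1 and homozygote 2 stood away from their own groups. In the muscle list homozygote 2 did, at 0.21 against -0.63 to -0.46 in the other homozygotes. Wild-type 1, at -0.20, lay near wild-type 2, at -0.11. Relative to the wild-type mean, the ribosomal protein list lay at -0.49 in wild-type 1, against -0.08 to 0.44 in the other wild-type larvae, and at -0.21 in homozygote 2, against -0.77 to -0.73 in the other homozygotes. The groups overlapped in all 3 lists, with exact permutation p = 0.0571, 0.0571 and 0.2.

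**Figure D2:**
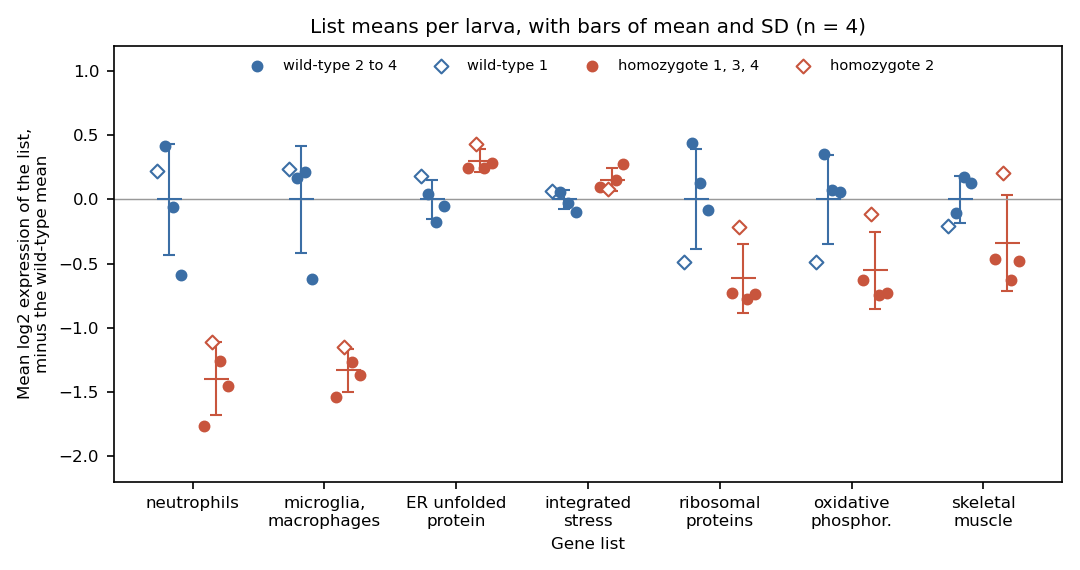
Mean log2 expression of 7 gene lists in each larva, less the wild-type mean of the list, with bars of mean and SD over the 4 larvae of a group and open diamonds for wild-type 1 and homozygote 2. The groups are apart for neutrophils, macrophages, the unfolded protein response and, narrowly, the integrated stress response. For ribosomal proteins wild-type 1, at -0.49, lies below homozygote 2, at -0.21.

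In total camera called 23 of 48 lists at its preset correlation, 6 higher and 17 lower, 0 with an estimated correlation (2 of them at an unadjusted p under 0.05) and 2 by fry. The list means of the groups did not overlap in 6 of the 48 lists, where chance gives about 1.4 on average. As lists vary together between larvae, no excess is read from this. Leaving out wild-type 1 and homozygote 2, edgeR called more genes in both directions on several lists: 10 higher and 2 lower of the unfolded protein response, 12 and 4 of the integrated stress response, 8 and 3 of heat shock, 4 and 1 of the synthetases, and 3 and 18 of the photoreceptors. That fit called 3952 of 21545 rows, 1694 higher and 2258 lower, so a larger count is not particular to these lists. Among the tested genes, 1 of 103 neighbours of osgep was called, counting 100 annotated genes on each side in the gene order of the GRCz12tu assembly, against 183 of 18184 genes elsewhere (two-sided Fisher's exact test, p = 1.0). That gene was fgd4b, 4.05-fold lower, named because it was the only call. Within 200 genes of osgep there were 3 calls, which included adm2a and aldh1l2.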

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

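Of the tests in this part, all but that of the genes around osgep were chosen after the results they measure had been seen. That one was planned in megabase windows, and its windows of 100 and 200 genes were chosen after the data were seen.

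When the 8 libraries were divided in each of the 35 possible ways into 4 and 4, chance was not excluded for the counts of genes: 2 of the 35 splits gave at least as many changed, lower and higher genes as the genotypes did. The genotypes gave 226, 165 and 61, and the highest other split gave 2134, 1496 and 638, while 33 of the 34 other splits gave fewer than 10 changed genes. The high split is the genotype split with wild-type 1 and homozygote 2 exchanged, and a count several times that of the genotypes points to a structure of the samples. For the lists called, 7 of the 35 splits gave at least the 23 of the genotypes, with 27 in the highest other split, so the number of lists called by camera at its preset correlation does not set the genotypes apart.

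The first pattern weighed is that exchange. A swap of labels between wild-type 1 and homozygote 2 is argued against by osgep: its log2 CPM in wild-type 1 minus homozygote 2 was 1.018, where the other 6 libraries predict -4.199 to 0.428 (95% interval) for a swap and -0.428 to 4.199 for the labels as given. A wrong label of wild-type 1 alone is argued against only narrowly: its 2.899 lay just above the interval for a homozygote (upper limit 2.862). Its mpx (6.323) and its neutrophil and macrophage means (0.224 and 0.235) lay above the homozygous limits of 5.224, -0.216 and -0.282, though these were picked for their fall. Its oxidative phosphorylation and ribosomal protein means (-0.485 and -0.489) went with the wrong label, below the wild-type limits of -0.235 and -0.431 and inside the homozygous intervals (-1.097 to -0.303 and -1.341 to -0.154). In these lists wild-type 1 and homozygote 2 had already been seen to stand away from their groups, so these means are not independent evidence. For a wrong label of homozygote 2 alone the values point both ways, so it stays open. Its osgep value of 1.881 lay inside the intervals of both genotypes (1.475 to 4.747 for wild-type, -0.410 to 2.862 for homozygous larvae), as did its neutrophil and macrophage list means, close to the lower wild-type limits (-1.109 and -1.154, limits -1.352 and -1.188). Its log2 CPM of mpx (4.087), grn1 (5.116) and fcer1gl (3.741), genes picked for their fall, lay below the wild-type intervals (lower limits 5.330, 5.870 and 3.900). In the other direction its oxidative phosphorylation mean of -0.115 lay above the homozygous interval (upper limit -0.303), in a list where it had already been seen to stand away. Its ribosomal protein mean of -0.214 lay inside the intervals of both genotypes (-0.431 to 0.757 for wild-type, -1.341 to -0.154 for homozygous larvae). Of 3944 genes called from the other 6 libraries, homozygote 2 was nearer the wild-type larvae in 2165 (54.9%) and wild-type 1 nearer the homozygotes in 2502 (63.4%), but each was so in 1 of the 24 neutrophil and macrophage genes among them. The neutrophil and macrophage lists were picked for a fall seen with both larvae under their given labels, so that count was partly set by the choice. Depth and a few abundant genes are argued against as well, since the exchanged split called 2023 genes after thinning of each library to the smallest total and 2065 without the 100 most abundant rows. Of its calls, 34 were shared with the genotypes, all in the same direction. As the 2 splits keep 6 of the 8 libraries on the same sides, no overlap due by chance is given. Its calls included 84 of 99 oxidative phosphorylation, 74 of 89 ribosomal protein and 34 of 65 muscle genes that were lower. They were lower on the side of wild-type 1 and homozygotes 1, 3 and 4, where 1 ribosomal protein gene was higher. Differences between larvae in growth, feeding or RNA quality remain open and were not tested.

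The second pattern is the lower level of neutrophil and macrophage genes. The structure just described is argued against as its whole source: with 1 surrogate variable in the fit the median log2 fold change of the 39 genes was -1.469, against -1.391 without it, and 37 lay below 0, although only 8 of the 16 calls remained. In the 8 lost, the median log2 fold change went from -1.925 to -1.803 and the median standard error from 0.317 to 0.394; the fold was smaller in 7 and the standard error larger in 6. None of the 8 had a p under 0.000524, the highest p called without the surrogate variable, so the adjustment over all rows alone did not end these calls. As the surrogate variable itself went partly with genotype, these losses do not show that the structure explains the fall. A loss of all blood lineages alike stays open: the fall exceeded that of the erythrocyte genes by a difference of -0.498 in mean log2 expression (-1.261 against -0.763; exact permutation p = 0.171). It exceeded that of the lymphoid genes by -0.944 and that of the blood stem and progenitor genes by -1.136 (exact permutation p = 0.0286 each, the smallest that 4 against 4 allows), which speaks against an equal fall of the RNA of these lists, but other cells of the larva may hold transcripts of both lists and so hide a loss of the cells. Fewer neutrophils and macrophages, or less RNA of these genes per cell, cannot be told apart in whole larvae. The SD of the fold changes over the 39 genes, 0.866, exceeded their median standard error of 0.323, but other cells of the larva may hold some of these transcripts.

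The third pattern is calls around osgep, where siblings sorted by genotype also differ in the linked haplotype. A strain or donor variant linked to osgep could place calls there, yet 1 of 103 neighbours was called, a share of 0.97% against 1.01% elsewhere (Fisher's exact test, p = 1.0). With about 1 call due by chance the test excludes neither a few linked genes nor an effect on adm2a or aldh1l2, which lie within 200 genes of osgep.

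In 10 of the 224 groups of 4 values searched, a library stood apart from the other 3 of its group; chance gives about 11.2. mmp13a was 114 CPM in wild-type 2 against 51.3 to 59.3 in the other wild-type larvae. psat1 was 24.45 CPM in wild-type 1 against 28.3 to 29.02. ppan, of ribosome biogenesis, was 8.64 CPM in wild-type 4 against 13.2 to 13.6. atf4a was 210.7 CPM in homozygote 2 against 140 to 149 in the other homozygotes, and fosab 9.293 CPM in homozygote 2 against 17.4 to 17.9. The total of homozygote 1 was 14398812 estimated counts, the lowest of its group, and the share of counts in the 10 most abundant genes was 13.6% in homozygote 2, the highest of its group. Relative to the wild-type mean, the ribosomal protein list stood at -0.2145 in homozygote 2, the macrophage list at -0.6193 in wild-type 4 and the lens crystallin list at -0.8739 in wild-type 4.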

How the results depend on the processing

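Among the tests here, scaling by library totals, leaving out wild-type 1 and homozygote 2 together, the surrogate variable and the windows counted in genes were chosen after the data were seen. The megabase windows planned around osgep were not run, because the gene table is of another assembly; within 200 genes of osgep on each side 3 genes were called, a share of 1.34% against 1% elsewhere.

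The 226 changed genes (61 higher, 165 lower) became 349 (114, 235) with no filter, where more rows were tested, 1683 (565, 1118) with DESeq2, 136 (34, 102) with voom, 15 (0, 15) against a 1.5-fold change, which asks for a larger change, and 123 (88, 35) with library totals. DESeq2 made 33 false calls among 180 on simulated data. With 1 surrogate variable there were 129 (18, 111), 74 of them shared, and without wild-type 1 and homozygote 2 there were 3952 (1694, 2258), 225 of the 226 among them; that pair was chosen because it stood apart, which inflates the count. With the replicate block there were 333 (72, 261), 180 of them shared, and 24 lists called. Same-numbered larvae had deviations that correlated at -0.08, 0.05, -0.08 and -0.11, which gives no sign of pairing by number. So few values do not exclude a shared clutch or day. Of the wild-type larvae, wild-type 2 alone correlated best with its own number. Leaving out each library in turn gave 38 to 2130 changed genes (6 to 871 higher, 32 to 1259 lower). Other settings stayed within 1.5 times of the counts. Where no reason is given, the cause was not tested.

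Of 51 called genes chosen by the naming rule, 17 kept the call whichever library was left out and 8 in every alternative run that tested them (ccl34b.8, c1qb, grn1, c1qa, fcer1gl, cxcl11.1, mpx and ripk3). Of these, ccl34b.8, c1qb, c1qa and cxcl11.1 had too few counts to be tested at a minimum count of 50, where 45 of the 51 kept the call. None of the 51 changed direction; 21 kept the call without wild-type 3, 28 with library totals, 29 with the surrogate variable and 8 against a 1.5-fold change. Signs turned in genes not called: tp53rk 0.21 with library totals and 0.0388 with the surrogate variable, osgepl1 0.00305 with the surrogate variable, and yrdc 0.00493 with voom, 0.38 with library totals, 0.32 with the surrogate variable and -0.14 to 0.13 with a library left out.

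Of the 23 lists called by camera, 0 were called with an estimated correlation, where 2 (neutrophils and macrophages) had an unadjusted p under 0.05, and 2 by fry, the same lists. With an estimated correlation the adjusted p was 0.431 for neutrophils and macrophages and 0.685 for the other called lists; that setting counts the correlation between genes of a list, up to 0.852 for lens crystallins. By fry it was 0.14 for the unfolded protein and integrated stress responses; 0.164 for ribosomal proteins, proteasome, erythrocytes, photoreceptors, NRF2 and heat shock; 0.214 for oxidative phosphorylation, inflammation and synthetases; 0.248 for glycolysis; 0.355 for cell cycle and cholesterol; 0.37 for lens, muscle, liver and ribosome biogenesis; 0.387 for intestine, 0.461 for mitochondrial ribosomes and 0.478 for exocrine pancreas. Without wild-type 1 and homozygote 2 calls were lost for inflammation (0.139), ribosome biogenesis (0.25), synthetases (0.506), cholesterol (0.254), heat shock (0.118) and the integrated stress response (0.0737). At a minimum count of 50 heat shock (0.101) and the integrated stress response (0.0535) were lost, and with library totals mitochondrial ribosomes (0.068) and cell cycle (0.086).

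With each library left out in turn, the adjusted p ranged from 2.15e-06 to 0.114 for exocrine pancreas, 8.82e-07 to 0.0682 for mitochondrial ribosomes, 4.16e-05 to 0.114 for liver, 9.21e-05 to 0.258 for ribosome biogenesis, 9.72e-05 to 0.15 for intestine, 0.00125 to 0.195 for cell cycle, 0.0022 to 0.256 for synthetases, 0.00199 to 0.161 for cholesterol, 0.00993 to 0.0935 for heat shock and 0.0279 to 0.0935 for the integrated stress response. The other called lists stayed below 0.05. In lists that were not called the direction turned for p53 (0.28 to 0.992 over the leave-outs) and neural progenitors (0.31 to 0.997, and 0.914 at a minimum count of 50). At the depth of these libraries, 43% of genes changed 2-fold were recovered in the simulation, so genes not called may still differ.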

Other observations

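All tests of lists assembled for this part were chosen after the results had been seen, and none is independent evidence.

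Medians of 5 other organ and housekeeping groups lay below 0, by amounts that moved with wild-type 1 and homozygote 2. Of 53 proteasome genes 50 had a log2 fold change below 0; psmf1, for a proteasome inhibitor subunit, fell by 0.98 on the log2 scale, 52 did not pass, and 28 were lower when adjusted over the list alone. Of 24 erythrocyte genes 21 lay below 0 and none passed, with 6 lower when adjusted over the list alone; the embryonic globin gene hbae1.1 was at 304 ± 115.3 CPM (SD, n = 4) in wild-type and 113.9 ± 58.1 CPM (SD, n = 4) in homozygous larvae (adjusted p = 0.0808 by edgeR). Of 55 liver genes 2 fell, the carboxylesterase gene ces3 (2.08-fold) and the vitamin D binding protein gene gc (1.89-fold), 53 did not pass, and 5 were lower when adjusted over the list alone. The calls of psmf1, ces3 and gc were lost without wild-type 2 or 3 or homozygote 1, 3 or 4 (highest edgeR adjusted p 0.137, 0.137 and 0.16). Of 46 lens crystallin genes none passed, with 15 lower and 1 higher when adjusted over the list alone (crygm2d20 log2 fold change -1.27); of 26 exocrine pancreas genes none passed either way (ctrb1 -1.05). Camera called these 5 lists (adjusted p = 1.64e-10 for proteasome, 9.46e-08 for erythrocytes, 0.00165 for liver, 3.16e-08 for lens and 0.00121 for pancreas), each with adjusted p = 0.685 with an estimated correlation; liver was lost without homozygote 1 and pancreas without wild-type 2 (0.114 each). From -0.488, -0.810, -0.254, -0.684 and -0.665 for proteasome, erythrocytes, liver, lens and pancreas, the medians went to -0.235, -0.696, -0.130, -0.878 and -0.058 with 1 surrogate variable. Without wild-type 1 and homozygote 2 they were -0.624, -1.018, -0.350, -0.553 and -1.137, with 27, 11, 20, 0 and 11 genes lower and 1, 0, 2, 1 and 0 higher. DESeq2 called 16, 4, 11, 15 and 1 genes of these lists lower and 1 lens gene higher. EdgeR without wild-type 4 called 9 lens genes lower. The calls of psmf1, ces3 and gc were lost with the surrogate variable (0.167, 0.0937 and 0.144) and with library totals (0.1, 0.061 and 0.0682).

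Camera also called mitochondrial ribosomal proteins, glycolysis, NRF2 targets and intestine lower and ribosome biogenesis and cholesterol synthesis higher (adjusted p = 0.00125, 0.00303, 0.00392, 0.0099, 0.00479 and 0.03415), with no member past edgeR's test of all 8 libraries with genotype alone and adjusted p = 0.685 with an estimated correlation for each. Adjusted over the list alone, 0 of 74 mitochondrial ribosomal, 2 lower and 1 higher of 42 glycolysis, 12 lower and 1 higher of 27 NRF2, 8 lower and 1 higher of 42 intestine, 7 higher of 87 ribosome biogenesis and 2 higher of 27 cholesterol genes passed; ppan and fdps had log2 fold changes of 0.78 and 0.66. With libraries scaled by totals alone the medians of mitochondrial ribosomal proteins, liver and intestine turned from -0.29, -0.25 and -0.22 to 0.11, 0.17 and 0.17, where the median of all genes moved to 0.40; relative to it they stood at -0.29, -0.23 and -0.23. With 1 surrogate variable the median of mitochondrial ribosomal proteins turned to 0.030, and those of glycolysis, NRF2 targets and intestine shrank from -0.398, -0.426 and -0.222 to -0.120, -0.192 and -0.167. Those of ribosome biogenesis and cholesterol synthesis grew from 0.145 and 0.235 to 0.211 and 0.358. Without wild-type 1 and homozygote 2 the 6 medians were -0.473, -0.515, -0.522, -0.364, 0.137 and 0.285, with 29, 20, 14, 14, 3 and 2 genes lower and 1, 2, 1, 1, 13 and 4 higher. In edgeR's fit with the replicate block 2 glycolysis, 1 NRF2 and 3 intestine genes were lower, and with library totals 3 ribosome biogenesis genes and 1 intestine gene were higher. With no filter 1 NRF2 and 3 intestine genes were lower, and 1 ribosome biogenesis and 1 cholesterol gene higher. At a minimum count of 50, 1 cholesterol gene was higher. Without the 100 most abundant rows 1 ribosome biogenesis and 1 cholesterol gene were higher.

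In lists drawn up after the results were seen, 7 of 44 amino acid transport and synthesis genes rose, 0 fell and 15 were higher when adjusted over the list alone. Among them were bcat1, slc1a4, aldh1l2, psat1 and asns, and the transporter gene slc6a15, 1.83-fold higher. By edgeR the call of slc6a15 was lost without wild-type 2, 3 or 4 or homozygote 1, 3 or 4 (highest adjusted p 0.164). The mean of the list was higher in each homozygote than in any wild-type larva, by 0.32 (exact permutation p = 0.0286). Of 30 AP-1 and immediate early genes 7 fell, among them ier2a (2.32-fold), junba (2.67-fold), jun (1.79-fold) and fosab (2.03-fold), and 12 were lower and 1 higher when adjusted over the list alone (difference of means -0.40, exact permutation p = 0.0571); ier2a was called whichever library was left out, and the calls of jun, junba and fosab were each lost without wild-type 2 or 3 or homozygote 1 or 3, those of jun and fosab also without homozygote 4 and that of fosab without wild-type 4 (highest edgeR adjusted p 0.102, 0.0941 and 0.115). Of the 7, junba and junbb are also on the inflammation list and cebpb on that of the integrated stress response, so their falls were counted there too. With library totals the calls of ier2a (0.0579), jun (0.0903), junba (0.0691) and fosab (0.15) were lost, and with 1 surrogate variable those of jun (0.0919), fosab (0.0937) and slc6a15 (0.132). Of 19 lymphoid genes none passed edgeR's test, and 3 were lower when adjusted over the list alone (difference -0.38, exact permutation p = 0.0286). For 16 genes of blood stem and progenitor cells the difference was -0.13 (exact permutation p = 0.0857).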
